A study of Mus musculus with 14 samples.

How the data were processed

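RNA was sequenced from mouse CD4 T cells polarized to the Th2 type, in 14 libraries of 4 groups: wild type and Ago1, Ago3 and Ago4 knockout, each at day 7 and day 14. Groups and replicate numbers were taken from the sample titles. The series text names the later time in a second way and mentions further samples, which are not analysed here.

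The reads were aligned with GSNAP version 2013-11-01 to GRCm38, per the submitters' processing notes. The authors deposited 1 table per library with a whole-number count of reads per gene and an RPKM value per gene, per the file headers. The counting tool and the gene annotation behind the counts are not given in the sources used here. Each deposited table holds 22598 genes, and 22457 of their Ensembl identifiers had a symbol in the GENCODE mouse annotation of release 21 (vM21), which also gave the coordinates, all in GRCm38. The RPKM values were used only to describe the libraries: the totals they imply matched 1 number per library, and the counts made up 41.3% of that total in wild type at day 7, 40.0% in knockout at day 7, 44.2% in wild type at day 14 and 43.3% in knockout at day 14. All tests used the counts. Reads of some genes with near-identical copies seem not to have been counted, since Gapdh stood at 0.288 to 1.19 CPM in the group means. Values of ribosomal genes, Ndufs5 and Hdac1 are therefore uncertain, as are those of overlapping genes, because the strandedness of the counting is not given.

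Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (11591), scaled by TMM, and fitted with the robust quasi-likelihood model with 1 mean per group over all 14 libraries (common biological coefficient of variation 0.354). The 5 comparisons were knockout against wild type at each day, the interaction of genotype and day, and day 14 against day 7 in each genotype. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are CPM on TMM-scaled totals. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Where all libraries of a group had 0 reads, a bound was computed against 3 counts over the group, and where a group had 1 to 3 reads, the ratio is given with an exact 95% counting interval.

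Before the data were examined, 35 gene lists (603 genes) were fixed for pathways, helper T cell types and other cell types, and 31 with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and again with a correlation estimated per list. Calls within a list were also counted with p-values adjusted over the list alone. The rule for named genes was fixed then too. It takes Ago1, Ago2, Ago3, Ago4, Sf3b3, Nisch, Il4, Il5, Il13, Il10 and Gata3, whatever their values. It takes the 8 called genes with the highest and the 8 with the lowest log2 fold change in each comparison, with a mean of the compared groups of at least 5 CPM and, except for the interaction, no overlap between libraries of the groups. Predicted genes, unnamed clones, Y-linked genes and Xist were left out of that part. It also takes up to 4 called members with the smallest adjusted p of each list described, and the most abundant member of each list for another cell type. A gene named by more than 1 part counts under each. Not every gene that this rule names is reported here.

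Alternatives fixed beforehand were other scaling factors, other count filters, fits of only the compared libraries, DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, the sequencing run as a term, a fold threshold, and leaving out each library in turn. The run term has 2 levels, read from the run identifiers of the deposited tables: all knockout day 7 libraries and wild-type day 7 libraries 2 to 4 belong to one, with wild-type day 14 library 2, and the other libraries to the other. Chosen after seeing the data were limma-voom without sample weights, and an offset that removes each library's trend over coding GC content and coding length (natural splines with 5 degrees of freedom, 11422 genes with coding sequence, 98.5%). Lists of melanocyte, keratinocyte and liver genes were added after seeing the data as well.

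The fitting steps were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. At day 7, 21% of 2-fold and 72% of 4-fold changes were recovered, on 11459 genes. At day 14, 9% and 62% were recovered (11468 genes), in the interaction 0% and 15% (11460), in wild type over time 11% and 63% (11463), and in knockout over time 8% and 75% (11451). Between 0 and 4 unchanged genes were called in each. The genes were drawn independently of each other, without library trends over GC content or coding length and without outlying libraries. These figures therefore do not cover false or missed calls from such structure in the real libraries.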

Results

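Gene expression was measured by paired-end RNA sequencing of mouse CD4 T cells in culture. Per the labels, naive cells sorted from the spleen were activated and polarized towards the Th2 type, the helper T cells of allergic and antiparasite responses. The 14 libraries form 4 groups: wild type at day 7 (n = 4), knockout at day 7 (n = 4), wild type at day 14 (n = 3) and knockout at day 14 (n = 3). The genotype label names a combined knockout of Ago1, Ago3 and Ago4, which encode Argonaute proteins that bind microRNAs. The labels do not say whether libraries of a group came from separate mice or separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Total counts per library ran from 23326248 to 35803197. Between 12534 and 13241 genes had at least 1 read in a library. In all 11591 genes entered the tests. No pair of libraries within a group agreed within sampling noise. Values below are CPM (mean ± SD) or log2 fold changes ± SE. Adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Floors and counting intervals cover counting error only.

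The targeted genes were looked at first, in every library. Ago1 (ENSMUSG00000041530, GRCm38 chromosome 4, 126435012 to 126468583) had 128 to 141 reads in the wild-type day 7 libraries and 67 to 100 reads in the wild-type day 14 libraries. All 4 knockout libraries of day 7 had 0 Ago1 reads, which is at least 161-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.000327). At day 14 the libraries labelled knockout held 2 Ago1 reads in all, a wild-type to knockout ratio of 139 with a 95% counting interval of 38.1 to 1154 (edgeR adjusted p = 0.00143). Ago3 (ENSMUSG00000028842, chromosome 4, 126331704 to 126429556) kept reads in every library labelled knockout, at 1.98 ± 0.206 CPM against 3.64 ± 0.789 CPM at day 7 (n = 4 each; log2 fold change -0.88 ± 0.30, edgeR adjusted p = 0.154). At day 14 Ago3 stood at 1.42 ± 0.188 CPM against 2.86 ± 1.35 CPM (n = 3 each; -1.01 ± 0.35, edgeR adjusted p = 0.136). Ago4 (ENSMUSG00000042500, chromosome 4, 126489541 to 126533472) stood at 3.17 ± 0.323 CPM in knockout against 0.617 ± 0.252 CPM in wild type at day 7. At day 14 Ago4 stood at 3.93 ± 1.34 against 1.46 ± 1.24 CPM, and it passed the test at neither day (edgeR adjusted p = 0.154 and 0.170). With a GC and coding length trend removed, 1 Argonaute gene was called higher and 1 lower at day 7. At day 14, 0 were called higher and 2 lower in that fit. Ago4 was the only Argonaute gene with a higher mean in knockout. Which parts of Ago3 and Ago4 were deleted is not given in the sources used here, so their counts do not check the genotype labels, and those of Ago1 do. Ago2, the Argonaute gene that was not targeted, stood at 94.0 ± 12.9 CPM in knockout and 126 ± 5.18 CPM in wild type at day 7 (-0.43 ± 0.15, edgeR adjusted p = 0.155). At day 14 Ago2 stood at 77.2 ± 11.5 and 117 ± 8.39 CPM (-0.59 ± 0.18, edgeR adjusted p = 0.0901).

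**Figure D1:**
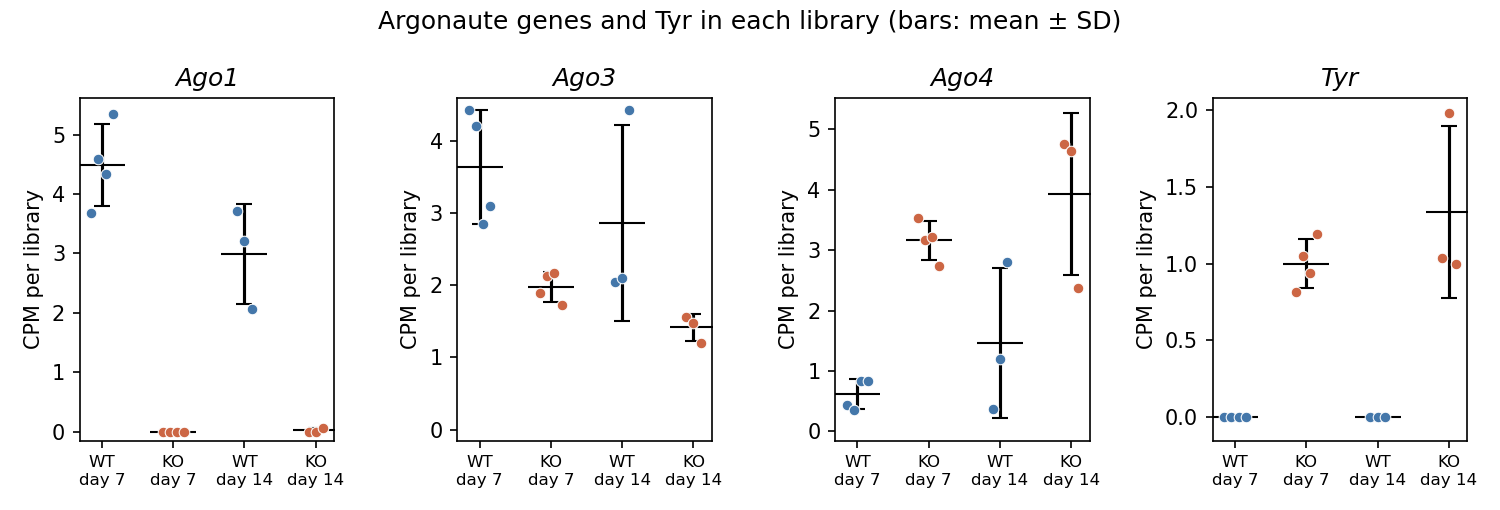
Levels of Ago1, Ago3, Ago4 and Tyr in CPM, with 1 point per library, grouped by genotype (WT wild type, KO knockout) and day, and bars for the mean ± SD. The libraries labelled knockout hold 0 to 2 Ago1 reads each, against 67 to 141 in wild type.

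The genotype comparison at day 7 asked what differs between knockout and wild-type Th2 cultures after 7 days. Near the targeted genes on chromosome 4, Hdac1 (ENSMUSG00000028800, 129516104 to 129542713), which encodes a histone deacetylase, was lower in knockout at 7.27 ± 1.17 CPM against 48.2 ± 8.27 CPM (n = 4 each; -2.73 ± 0.27, edgeR adjusted p = 0.000327). Zbtb8a, a zinc finger gene (129353628 to 129378116), fell from 6.37 ± 0.768 to 0.227 ± 0.174 CPM (-4.83 ± 0.51, edgeR adjusted p = 0.000528). Ndufs5, a gene of mitochondrial complex I (123712710 to 123718202), was lower by -2.68 ± 0.43 (edgeR adjusted p = 0.0249). Cap1 (122859047 to 122886056), which encodes an actin-binding protein, was higher in knockout at 299.8 ± 43.1 CPM against 66.7 ± 7.67 CPM (2.17 ± 0.23, edgeR adjusted p = 0.00055). Within 10 Mb of the Argonaute genes lay 4 of the 10 called genes other than the targets, against 232 of 11587 tested genes. On other chromosomes, Tanc1, a synaptic scaffold gene, fell from 29.6 ± 7.77 to 4.17 ± 1.62 CPM (-2.83 ± 0.38, edgeR adjusted p = 0.00437). Slc30a3, a zinc transporter gene, rose from 0.0278 ± 0.0557 to 3.37 ± 0.765 CPM (6.55 ± 0.78, edgeR adjusted p = 0.00159). Mgl2, a C-type lectin gene of macrophages and dendritic cells, was higher by 2.28 ± 0.37 (edgeR adjusted p = 0.0249).

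A pair of pigment genes separated the genotypes in every library. Tyr (ENSMUSG00000004651, chromosome 7, 87424771 to 87493512), which encodes the first enzyme of melanin synthesis, had 0 reads in all wild-type libraries and 1.00 ± 0.160 CPM in knockout at day 7, at least 40.6-fold higher against the group floor (edgeR adjusted p = 0.00393). Nonagouti (symbol a, ENSMUSG00000027596, chromosome 2, 154791402 to 155051012), which encodes a signal for yellow pigment, had 74 to 123 reads in each knockout library and 0 to 2 in wild type, a ratio of 214 with a 95% counting interval of 58.8 to 1773 (edgeR adjusted p = 0.00182). At day 14 Tyr was at least 39.7-fold higher and nonagouti had 117 to 159 against 0 to 8 reads (5.61 ± 0.86, edgeR adjusted p = 0.00505 and 0.00823). Tyr, nonagouti, Slc30a3, Zbtb8a, Ndufs5, Mgl2 and the remaining call, the predicted gene Gm8797 (1.68 ± 0.28, edgeR adjusted p = 0.0305), fall outside the rule for named genes and were chosen after their values were seen.

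Several gene groups fixed beforehand stood apart at day 7 as groups, while their members other than Ago1 stayed below the threshold over all genes. All of these calls rest on the preset correlation, and 0 of the 11 groups stayed past the threshold with an estimated correlation. The median of the 33 interferon-stimulated genes, which restrain viruses, was 2.29 higher in knockout on the log2 scale (camera adjusted p = 5.25e-14, adjusted p = 0.458 with an estimated correlation). Of these, 0 passed the threshold over all genes and 24 were higher when adjusted over the list alone. The 44 genes of the cytosolic ribosome, whose counts are uncertain because of near-identical gene copies, had a median of 0.71 (camera adjusted p = 1.13e-13, adjusted p = 0.505 with an estimated correlation), with 0 over all genes and 25 higher adjusted over the list alone. The 37 genes of oxidative phosphorylation had a median of 0.52 (camera adjusted p = 1.22e-09, adjusted p = 0.528 with an estimated correlation), with 0 and 18 higher. Of the microRNA pathway, 23 genes other than Ago1, Ago3 and Ago4 had a median of -0.68 (camera adjusted p = 9.72e-05, adjusted p = 0.458 with an estimated correlation), with 0 over all genes and 8 lower adjusted over the list alone. Markers of myeloid and dendritic cells (7 genes tested, median 1.34, camera adjusted p = 0.000285) and of major histocompatibility class II (6 genes, median 1.46, camera adjusted p = 0.000847) were higher as groups, with 6 and 4 higher adjusted over the list alone. Immediate early genes (17 genes, median 0.65), cholesterol synthesis (24 genes, 0.43), T cell activation (18 genes, 0.72) and cytotoxic genes (9 genes, 0.78) also passed camera in the higher direction (adjusted p = 0.0038, 0.00596, 0.0107 and 0.0469). Of their members 5, 0, 2 and 2 were higher adjusted over the list alone, and 1 cytotoxic gene was lower. The list of 4 Argonaute genes, which holds the targeted genes and so is not independent of the design, passed camera in the lower direction (median -0.65, camera adjusted p = 0.00108, 1 lower over all genes, and 3 lower and 1 higher adjusted over the list alone). The slope of log2 CPM over coding length stood at -0.145 ± 0.175 per doubling in knockout and 0.196 ± 0.0969 in wild type, without overlap (n = 4 each; exact permutation test, two-sided p = 0.0286, the smallest possible, adjusted p = 0.114). With a GC and coding length trend removed, an alternative chosen after seeing the data, the ribosomal median was 0.24, that of oxidative phosphorylation 0.14 and that of the Argonaute genes -0.21, and these lists still passed camera (adjusted p = 0.000453, 0.0103 and 0.0334). The microRNA pathway call ended with it (median -0.19, camera adjusted p = 0.158), and so did the cytotoxic call (median 0.37, camera adjusted p = 0.158). With an estimated correlation the Argonaute list was at adjusted p = 0.123 and the 6 others between 0.458 and 0.649.

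Genes named in the series title or tied to Th2 function did not pass the test at day 7. Sf3b3, which encodes a subunit of the splicing complex SF3b, stood at 413 ± 160 CPM in knockout and 718 ± 44.3 CPM in wild type (-0.80 ± 0.30, edgeR adjusted p = 0.157). Nisch was at -0.56 ± 0.23 (edgeR adjusted p = 0.177). Il4, the cytokine that drives Th2 cells, stood at 2.83 ± 1.15 against 1.36 ± 0.359 CPM (1.06 ± 0.48, edgeR adjusted p = 0.200). Il10 (0.14 ± 0.70), Gata3, the Th2 transcription factor (0.02 ± 0.15), and Il5 (0 to 3 reads per library) stayed below the threshold too (edgeR adjusted p = 0.922, 0.947 and 0.275). Il13 had 0 reads in all libraries of day 7. The list of 20 tested Th2 genes had a median of 0.27 (camera adjusted p = 0.266), the 13 SF3a and SF3b genes -0.33 (0.857) and the 44 other splicing genes 0.15 (0.266), each with 0 members past the threshold over all genes. With the GC and coding length trend removed these medians were 0.26, 0.02 and 0.04 (camera adjusted p = 0.344, 0.580 and 0.649).

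At day 7 6 genes were higher and 5 lower of 11591 tested, and 2716 had an unadjusted p under 0.05. Without 1 library at a time the count ranged from 8 to 10, and 8 calls held each time. Ndufs5, Mgl2 and Gm8797 were lost in most of these fits, with adjusted p up to 0.178, 0.146 and 0.203. All 3 were also lost with a term for the sequencing run (edgeR adjusted p = 0.0609, 0.0626 and 0.0666), which left 8 calls. Without knockout library 4, the medians were 1.37 for the interferon, 0.43 for the ribosomal and 0.82 for the myeloid list. In that fit T cell activation and cholesterol synthesis lost their calls (camera adjusted p = 0.0934 and 0.0659). The cytotoxic call ended without any 1 of 4 libraries (wild-type 1 and 2, knockout 1 and 4; camera adjusted p = 0.105, 0.0555, 0.0502 and 0.108).

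**Figure D2:**
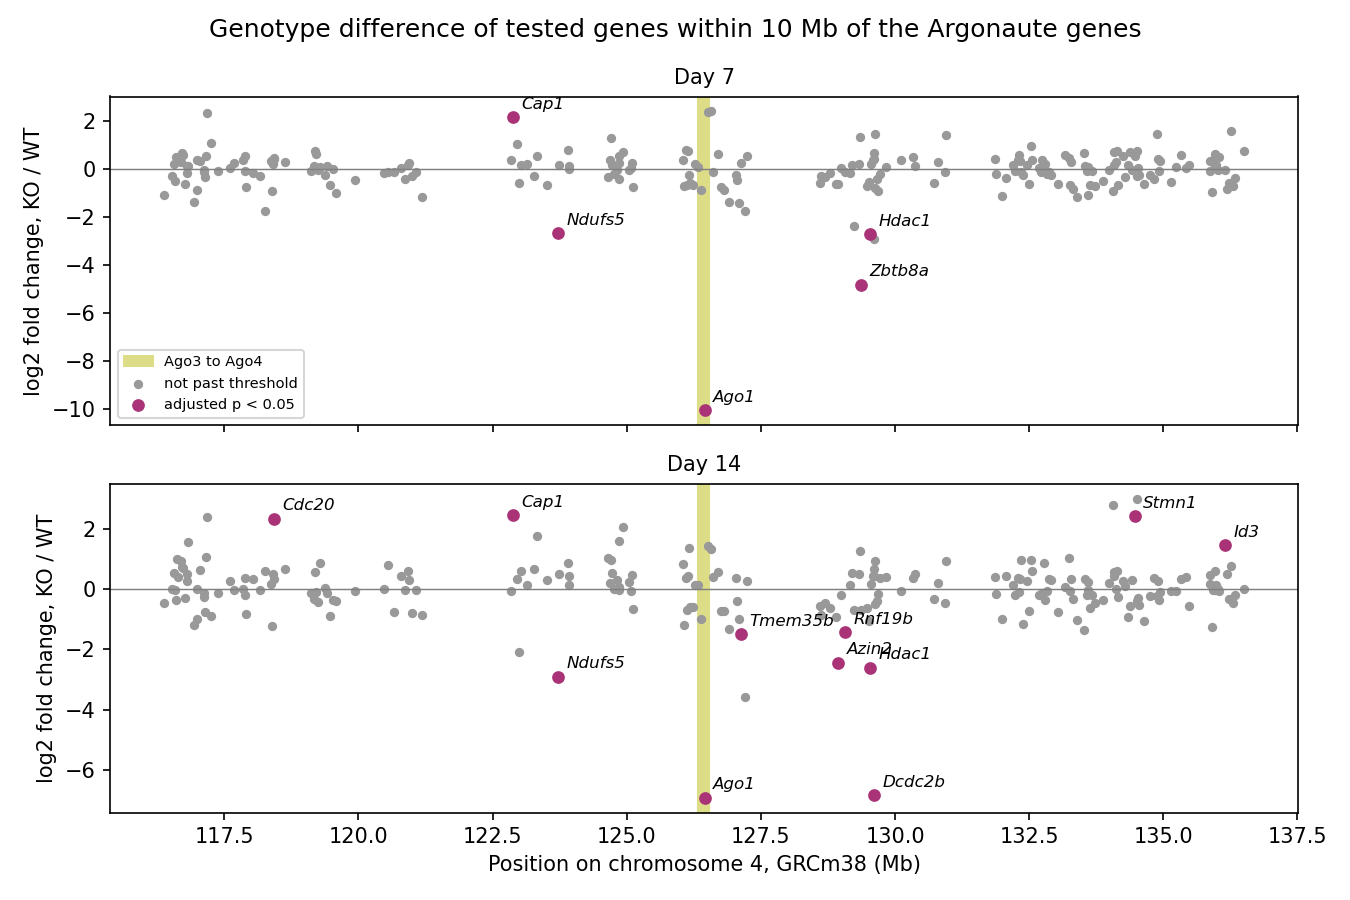
Log2 fold change, knockout over wild type, of tested genes by position on chromosome 4 (Mb, GRCm38) within 10 Mb of the Argonaute genes, at each day. Labelled points are past the threshold, with Hdac1, Zbtb8a and Ndufs5 lower and Cap1 higher at day 7.

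The genotype comparison at day 14 asked the same of cultures a week older. Txk, a T cell kinase gene, stood at 16.3 ± 3.10 against 2.39 ± 0.208 CPM (n = 3 each; 2.77 ± 0.28, edgeR adjusted p = 0.000758). Ms4a4b and Ms4a6b, membrane protein genes of naive T cells, stood at 195 ± 76.4 against 27.7 ± 17.5 CPM and at 174 ± 62.2 against 25.7 ± 9.43 CPM (2.82 ± 0.49 and 2.75 ± 0.32, edgeR adjusted p = 0.0125 and 0.00128). From the list of 17 tested naive and memory genes, 3 were higher over all genes and 0 lower, among them Dapl1 (3.94 ± 0.58, edgeR adjusted p = 0.00642) and Id3 (1.45 ± 0.26, 0.0156). Adjusted over the list alone 5 were higher, and the list passed camera with a median of 0.18 (camera adjusted p = 0.00795, adjusted p = 0.539 with an estimated correlation).

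Th2 genes were lower in knockout as a group at day 14 only with wild-type library 3 in the fit. Without it the list's median was -0.10 and the call ended (camera adjusted p = 0.312). Nfil3, a transcription factor gene that acts in Th2 cytokine control, stood at 448 ± 157 against 1434 ± 179 CPM (-1.68 ± 0.26, edgeR adjusted p = 0.00823). Il4ra, the receptor chain for IL-4 and IL-13, stood at 2396 ± 1229 against 6583 ± 1085 CPM (-1.46 ± 0.32, 0.0369). Of the 20 tested Th2 genes these 2 were lower over all genes and 0 higher. Adjusted over the list alone 3 were lower, and the list's median was -0.80 (camera adjusted p = 0.00795, adjusted p = 0.539 with an estimated correlation). Inhibitory receptors were lower as a group (8 genes, median -0.65, camera adjusted p = 0.0145, adjusted p = 0.539 with an estimated correlation; 2 lower over all genes, 3 adjusted over the list alone). Tigit stood at 3.19 ± 1.22 against 29.4 ± 12.9 CPM (-3.20 ± 0.63, edgeR adjusted p = 0.024). Pdcd1, which encodes PD-1, stood at 2.59 ± 1.24 against 13.8 ± 2.13 CPM (-2.41 ± 0.53, 0.039). Il4 (0.27 ± 0.52), Il5 (-1.31 ± 0.86), Il10 (-1.93 ± 0.68), Gata3 (0.24 ± 0.17), Sf3b3 (-0.38 ± 0.34) and Nisch (-0.64 ± 0.27) did not pass (edgeR adjusted p = 0.798, 0.394, 0.138, 0.419, 0.530 and 0.188). Il13 had 3 to 5 reads per wild-type library and 0 to 5 per knockout library and was not tested.

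Cell division genes were higher in knockout as groups. The 27 tested genes of the G2 and M phases had a median of 1.83 (camera adjusted p = 8.1e-13, adjusted p = 0.539 with an estimated correlation). Over all genes 2 were higher and 0 lower, and 10 were higher adjusted over the list alone. The 2 genes past the threshold over all genes were Cdc20, an activator of anaphase (259.8 ± 100.3 against 51.6 ± 36.6 CPM, 2.33 ± 0.44, edgeR adjusted p = 0.0209), and Plk1, a mitotic kinase gene (177 ± 75.5 against 30.9 ± 28.2 CPM, 2.51 ± 0.55, 0.0362). Cks1b, a partner of cyclin-dependent kinases, was higher by 2.62 ± 0.48 (edgeR adjusted p = 0.0162). The 29 S phase genes had a median of 1.07 (camera adjusted p = 5.42e-09, adjusted p = 0.539 with an estimated correlation), with 0 over all genes and 15 higher adjusted over the list alone. In the wild-type day 14 libraries the median deviation of the G2 and M genes ran from -1.06 to 2.67 on the log2 scale, with library 3 at the upper end, and in the knockout day 14 libraries from 2.59 to 3.26.

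With an estimated correlation 0 of the 12 groups past camera at day 14 stayed past the threshold. Groups past camera besides those above were oxidative phosphorylation (37 genes, median 0.59, camera adjusted p = 2.18e-08; Atp5c1 higher over all genes at 0.92 ± 0.21, edgeR adjusted p = 0.0439; 16 higher adjusted over the list alone). So were ribosomal genes (44, median 0.57, camera adjusted p = 7.9e-07; 0 and 2 higher) and other splicing genes (44, median 0.35, camera adjusted p = 0.00185; 0 and 8 higher). Interferon-stimulated genes (33, median 0.77, camera adjusted p = 0.00795, adjusted p = 0.806 with an estimated correlation) had 0 members past the threshold either way, and the call ended without wild-type library 2 (camera adjusted p = 0.174). The microRNA pathway (23, median -0.43, camera adjusted p = 0.0145, adjusted p = 0.539 with an estimated correlation) had 0 members past it either way too. Cytotoxic genes (9, median 1.41, camera adjusted p = 0.00795) also passed. Over all genes 1 of them was higher, the granule gene Nkg7 (18.2 ± 12.8 against 2.63 ± 0.963 CPM, 2.78 ± 0.57, edgeR adjusted p = 0.0309), with 4 higher and 1 lower adjusted over the list alone. The Argonaute list, with Ago1 in it, again passed in the lower direction (median -0.80, camera adjusted p = 0.00159; 1 lower over all genes, 3 lower and 1 higher adjusted over the list alone). With the GC and coding length trend removed the microRNA pathway call ended (median -0.16, camera adjusted p = 0.202), and so did the cytotoxic call (median 1.12, camera adjusted p = 0.0672). The ribosomal median was then 0.22 and that of oxidative phosphorylation 0.31. With an estimated correlation the Argonaute list was at adjusted p = 0.125, the ribosomal at 0.603 and the others of this paragraph, the interferon list aside, at 0.539.

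Markers of mast cells moved in single genes, without the list passing camera (4 genes tested, median 1.72, adjusted p = 0.0646). Cpa3, a mast cell protease gene, stood at 52.3 ± 59.1 against 3.76 ± 2.43 CPM (3.80 ± 0.77, edgeR adjusted p = 0.0270). Kit, the receptor for stem cell factor, stood at 7.02 ± 4.33 against 0.0660 ± 0.0622 CPM (6.63 ± 1.11, 0.0115). The globin gene Hba-a1 had 64 knockout reads and 1 wild-type read, a ratio of 60.5 with a 95% counting interval of 10.5 to 2428 (edgeR adjusted p = 0.0115). Fcgr3, an Fc receptor gene of myeloid cells, was lower by -1.82 ± 0.38 (0.0309). Also among the genes with the highest fold changes were Bpifb4 (3.48 ± 0.57) and Ptger3, a prostaglandin E receptor gene (3.18 ± 0.73), both higher (edgeR adjusted p = 0.0311 and 0.0457). Lower were Slc4a4, a bicarbonate transporter gene (-4.49 ± 0.78), Adamtsl3 (-4.26 ± 0.74), Acat3 (-3.40 ± 0.71), Gpm6b (-3.39 ± 0.69), Tnfrsf8, which encodes CD30 (-2.88 ± 0.66), Baiap3 (-2.81 ± 0.56) and Adamtsl4 (-2.76 ± 0.61), at edgeR adjusted p = 0.0125, 0.013, 0.0315, 0.0303, 0.0452, 0.0262 and 0.0381.

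Across all genes 98 were higher and 67 lower at day 14, 94 and 65 of them by at least 2-fold, with 2515 at an unadjusted p under 0.05. A fit of the 6 day 14 libraries alone called 0 genes (edgeR, 1157 at an unadjusted p under 0.05, smallest adjusted p = 0.183). On all libraries the count was 924 with DESeq2, 420 with limma-voom without sample weights and 79 with a run term in edgeR. With the run term 20 of 33 named and called genes kept their calls. Those lost include Il4ra and Pdcd1 (edgeR adjusted p = 0.0864 each), Plk1 (0.0798), Nkg7 (0.0649), Atp5c1 (0.0871), Fcgr3 (0.0756), Bpifb4 (0.0864), Ptger3 (0.0944), Tnfrsf8 (0.0884), Acat3 (0.0691), Adamtsl4 (0.0843) and Baiap3 (0.0619). Leaving out 1 library moved the count to 49, 53 or 2640 without wild-type library 1, 2 or 3, and to 289, 605 or 42 without knockout library 1, 2 or 3. Of 33 named and called genes 10 held each time (Ago1, Tyr, nonagouti, Slc30a3, Dcdc2b, Txk, Ms4a4b, Ms4a6b, Dapl1 and Nfil3). Without knockout library 3 many calls ended, among them Tigit (edgeR adjusted p = 0.139), Pdcd1 (0.150), Il4ra (0.177), Cdc20 (0.115), Plk1 (0.160), Nkg7 (0.151), Tnfrsf8 (0.200), Ptger3 (0.183), Acat3 (0.122), Gpm6b (0.123), Baiap3 (0.150), Adamtsl4 (0.175), Slc4a4 (0.0893) and Adamtsl3 (0.0825). The naive list call ended without wild-type library 3 or knockout library 1 (camera adjusted p = 0.460 and 0.142), and that of the microRNA pathway without wild-type library 3 or knockout library 3 (0.282 and 0.109). The inhibitory receptor call ended without wild-type library 3, knockout library 2 or knockout library 3 (camera adjusted p = 0.168, 0.0893 and 0.0508). The medians without wild-type library 3 were 4.09 for G2 and M and 1.68 for S phase.

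The overlap of the genotype calls asked whether the same genes differ at both days. Cap1, Mgl2, Slc30a3, Tyr and nonagouti were higher at both days, 5 genes where independent lists would share 0.0507. Ago1, Hdac1 and Ndufs5 were lower at both, 3 genes against 0.0289. These comparisons share no libraries, but that does not make their lists independent. The labels do not say whether the cultures of both days came from the same mice. Both lists also use the spread estimated jointly over all libraries. The numbers for independent lists are therefore only a rough guide. With fits of only the compared libraries the overlap was 0, as day 14 then had 0 calls. All 11 genes called at day 7 had the same direction at day 14. Of the 165 genes called at day 14, 120 (72.7%) had the same direction at day 7, against 70.7% of all tested genes.

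The interaction asked which genes differ between genotypes by another amount at day 14 than at day 7. Txk stood at 54.5 ± 10.5 CPM in wild type and 38.0 ± 8.70 CPM in knockout at day 7, and at 2.39 ± 0.208 and 16.3 ± 3.10 CPM at day 14 (difference of log2 fold changes 3.29 ± 0.35, edgeR adjusted p = 0.00169). Ms4a6b (2.42 ± 0.40), Gramd3 (2.21 ± 0.30) and P2ry1, a receptor gene for extracellular ADP (2.15 ± 0.35), were positive in the interaction too (edgeR adjusted p = 0.0370, 0.0152 and 0.0370). The genotype difference of Ms4a6b was 0.33 ± 0.26 at day 7 and 2.75 ± 0.32 at day 14. Gramd3 stood at 152 ± 17.8 and 133 ± 14.9 CPM at day 7, and at 10.1 to 12.5 CPM in wild type and 35.0 to 60.8 CPM in knockout at day 14. Tigit went the opposite way, at 1.93 ± 0.988 and 7.09 ± 5.81 CPM at day 7 and 29.4 ± 12.9 and 3.19 ± 1.22 CPM at day 14 (-5.09 ± 0.82, edgeR adjusted p = 0.0370). Kit (8.23 ± 1.32), Zbtb8a (4.13 ± 0.68) and the sodium pump gene Atp1b1 (3.13 ± 0.54) were positive (edgeR adjusted p = 0.0370, 0.0370 and 0.0479). Batf3, a transcription factor gene (-3.84 ± 0.64), and Bspry (-2.51 ± 0.41) were negative (edgeR adjusted p = 0.0372 and 0.0370). Kit, Zbtb8a and Batf3 fall outside the rule for named genes. Among the fixed genes none passed, with Il4 at -0.79 ± 0.71 (edgeR adjusted p = 0.921), Il10 at -2.07 ± 0.97 (0.626) and Sf3b3 at 0.41 ± 0.45 (0.956).

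Of 11591 genes 7 were positive and 3 negative in the interaction (924 at an unadjusted p under 0.05), and 13 of 31 lists passed camera, 0 of them with an estimated correlation. Upper-quartile scaling gave 8 positive and 7 negative, and removal of a GC and coding length trend 32 and 42. With a run term only Txk stayed past the threshold (edgeR adjusted p = 0.0140), and it was also the only call to hold without any 1 library (highest adjusted p = 0.0160). The count was 380 without wild-type day 14 library 3, 16 without knockout day 14 library 1, 10 without knockout day 7 library 4, and 1 to 4 without any other library.

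Time in wild-type cultures asked how Th2 cells change from day 7 to day 14. Th2 cytokine and regulator genes rose, 15 of 20 over all genes and 0 lower (16 higher adjusted over the list alone, median 2.59, camera adjusted p = 3.83e-10, adjusted p = 0.0646 with an estimated correlation). Il4 rose from 1.36 ± 0.359 CPM (n = 4) to 8.01 ± 6.90 CPM (n = 3; 2.56 ± 0.51, edgeR adjusted p = 0.00268), Il5 from 0 reads to 24 to 303 reads per library, at least 205-fold (0.000607). Library 3 was the highest at day 14 for both, with Il4 at 15.9 CPM against 3.12 and 5.01 CPM in libraries 1 and 2. Il10 rose from 0.432 ± 0.185 to 39.0 ± 35.6 CPM (6.48 ± 0.75, edgeR adjusted p = 5.63e-05). Gata3 did not pass (-0.29 ± 0.16, edgeR adjusted p = 0.234). Nfil3 (2.15 ± 0.24, edgeR adjusted p = 3.95e-05) and Ecm1, a matrix protein gene of Th2 migration (6.18 ± 0.86, 0.000226), rose. Naive and memory genes fell, 14 of 17 over all genes with 1 higher (the same numbers adjusted over the list alone), with a median of -1.90 (camera adjusted p = 8.46e-17, adjusted p = 0.0287 with an estimated correlation). Among them were Dapl1 (-7.00 ± 0.59, edgeR adjusted p = 5.12e-06), Id3 (-2.70 ± 0.26, 1.48e-05) and Foxo1 (-1.90 ± 0.21, 3.15e-05).

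Cytotoxic and Th1 genes rose too in wild type. Gzma, a granzyme gene, went from 0.921 ± 0.426 to 1466 ± 1807 CPM (10.64 ± 1.17, edgeR adjusted p = 3.87e-05), and Gzmb by 8.26 ± 1.06 (0.000124). The day 14 mean of Gzma rests largely on library 3, at 3534 CPM against 193 and 670 CPM in libraries 1 and 2. Cytotoxic genes were higher in 6 of 9 (7 higher and 1 lower adjusted over the list alone, median 1.98, camera adjusted p = 0.00134, adjusted p = 0.409 with an estimated correlation). Th1 genes were higher in 9 of 15 and lower in 0 (median 1.79, camera adjusted p = 3.98e-06, adjusted p = 0.00983 with an estimated correlation). Among them were Il12rb1 (3.42 ± 0.28), Il18rap (4.62 ± 0.54), Hlx (4.17 ± 0.51) and Cxcr3 (3.55 ± 0.55), all at edgeR adjusted p of 0.000486 or less. Cholesterol synthesis genes rose in 16 of 24 and fell in 0 (17 adjusted over the list alone, median 1.20, camera adjusted p = 7.33e-08, adjusted p = 0.352 with an estimated correlation). Acat2 rose by 2.64 ± 0.36 and the lanosterol synthase gene Lss by 1.93 ± 0.29 (edgeR adjusted p = 0.000169 and 0.000374). Of the unfolded protein response 12 of 22 rose (median 0.66, camera adjusted p = 0.000575, adjusted p = 0.398 with an estimated correlation), with its regulator Xbp1 at 2.13 ± 0.27 (edgeR adjusted p = 0.000115). Of p53 targets 9 of 18 rose and 1 fell (median 0.93, camera adjusted p = 0.000846, adjusted p = 0.0835 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 4.50 ± 0.68 (edgeR adjusted p = 0.000406). In the wild-type fit G2 and M genes passed with 14 of 27 higher (22 adjusted over the list alone, median 2.31, camera adjusted p = 0.000734, adjusted p = 0.658 with an estimated correlation). Examples are Birc5 (4.08 ± 0.78, edgeR adjusted p = 0.00207) and Ccna2 (4.82 ± 1.07, 0.00529). S phase genes passed with 11 of 29 higher (median 0.60, camera adjusted p = 0.026, adjusted p = 0.692 with an estimated correlation). Both calls rest on wild-type day 14 library 3. Without it they ended (camera adjusted p = 0.564 and 0.895), with the G2 and M median at 0.14.

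Mast cell genes fell in wild type from day 7 to day 14, 3 of 4 over all genes (median -4.03, camera adjusted p = 0.00629, adjusted p = 0.0762 with an estimated correlation). Cpa3 went from 47.0 ± 14.0 to 3.76 ± 2.43 CPM (-3.65 ± 0.74, edgeR adjusted p = 0.00315), Kit by -5.61 ± 1.07 (0.00208) and Tpsb2, a tryptase gene, by -4.42 ± 1.30 (0.0307). The B cell list did not pass (3 genes tested, median -1.32, camera adjusted p = 0.866). The 7 myeloid genes rose as a group, at a median of 1.47 (4 higher over all genes, camera adjusted p = 0.00444, adjusted p = 0.410 with an estimated correlation). The most abundant of them was Cst3 (129 ± 34.8 to 357 ± 62.3 CPM, 1.47 ± 0.30, edgeR adjusted p = 0.00328). Eomes, the most abundant marker on the CD8 T cell list, went from 4.69 ± 1.44 to 31.5 ± 9.90 CPM (2.74 ± 0.44, edgeR adjusted p = 0.000584). The whole CD8 list summed to 12.7 ± 0.621 and 38.8 ± 10.1 CPM. Its rise was therefore that of Eomes, which is also on the Th1 list, and not of its other members. Treg genes rose in 9 of 13 and fell in 1 (median 1.38, camera adjusted p = 0.000423, adjusted p = 0.0762 with an estimated correlation). Tigit rose by 3.94 ± 0.58 and Tnfrsf9 by 5.50 ± 0.87 (edgeR adjusted p = 0.000351 and 0.000554). T cell activation genes (8 of 18 higher, 1 lower, median 0.95, camera adjusted p = 0.020, adjusted p = 0.489 with an estimated correlation) and glycolysis genes (5 of 20 higher, median 0.43, camera adjusted p = 0.0305, adjusted p = 0.640 with an estimated correlation) also passed camera.

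The highest rises by the rule were the cytokine gene Il24 (at least 767-fold), Sval1 (at least 552-fold) and Thbs4 (at least 418-fold), each at 0 reads at day 7. They were followed by Mcf2l (10.73 ± 1.02), Gzma, Foxf2 (ratio 1246, 95% counting interval 344 to 10293), the cathepsin gene Ctsh (8.70 ± 0.89) and Pilrb1 (8.39 ± 0.95), all at edgeR adjusted p of 0.00263 or less. The lowest were Dapl1, Actn1 (-5.30 ± 0.59), Cd9 (-4.83 ± 0.61), Ifitm10 (-4.52 ± 0.72), Txk (-4.51 ± 0.29), Gpr183, which encodes a migration receptor (-4.34 ± 0.29), the carbonic anhydrase gene Car2 (-4.23 ± 0.50) and Cpm (-4.20 ± 0.38), all at edgeR adjusted p of 0.000586 or less. Over all genes 1525 were higher and 850 lower (3768 at an unadjusted p under 0.05; 1258 and 592 by at least 2-fold). In all 14 of 31 lists passed camera, 2 with an estimated correlation. The median of all genes was 0.11 with upper-quartile scaling, and -0.13 with the GC and coding length trend removed, with 1657 higher and 2165 lower, so the share of higher genes depends on scaling. Without wild-type day 14 library 3 the count was 3539, Ccna2 lost its call (edgeR adjusted p = 0.0830), and so did the mast cell and T cell activation groups (camera adjusted p = 0.112 and 0.0595). The glycolysis call ended without wild-type day 14 library 1 or 2 (camera adjusted p = 0.0689 and 0.112), and a run term left 2145 genes but ended the calls of S phase (camera adjusted p = 0.139) and of Ccna2 (edgeR adjusted p = 0.0928). The glycolysis call also ended with the GC and coding length trend removed (camera adjusted p = 0.0794).

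Time in knockout cultures asked the same question in the other genotype. Cell division genes rose, 23 of 27 in G2 and M with 0 lower (25 adjusted over the list alone, median 3.58, camera adjusted p = 3.67e-18, adjusted p = 0.232 with an estimated correlation). In S phase 20 of 29 rose with 0 lower (23 adjusted over the list alone, median 1.98, camera adjusted p = 3.07e-13, adjusted p = 0.270 with an estimated correlation). Among them were Cdc20 (3.05 ± 0.41, edgeR adjusted p = 0.000283), Plk1 (3.46 ± 0.51, 0.000485), the survivin gene Birc5 (5.17 ± 0.78, 0.000608) and Mcm5, a helicase subunit of replication (2.89 ± 0.45, 0.000716). Th2 genes rose in 11 of 20 and fell in 0 (13 adjusted over the list alone, median 2.02, camera adjusted p = 6.73e-06, adjusted p = 0.204 with an estimated correlation). Il4 went from 2.83 ± 1.15 CPM (n = 4) to 9.69 ± 2.54 CPM (n = 3; 1.77 ± 0.50, edgeR adjusted p = 0.0254). Il5 rose by 5.05 ± 1.06 (edgeR adjusted p = 0.00804) and Il10 by 4.40 ± 0.71 (0.000901), while Gata3 did not pass (-0.07 ± 0.16, 0.848). Naive and memory genes fell in 12 of 17 and rose in 2 (15 lower adjusted over the list alone, median -1.52, camera adjusted p = 1.08e-12, adjusted p = 0.0649 with an estimated correlation). Dapl1 stood at -4.40 ± 0.47 and Lef1, a transcription factor gene of naive cells, at -1.52 ± 0.23 (edgeR adjusted p = 6.62e-05 and 0.000608).

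Cytotoxic genes rose in 5 of 9 in knockout (6 adjusted over the list alone, median 1.73, camera adjusted p = 2.15e-06, adjusted p = 0.204 with an estimated correlation). Nkg7 stood at 4.48 ± 0.56, Gzma at 6.84 ± 1.01 and Gzmb at 8.07 ± 1.05 (edgeR adjusted p = 0.000166, 0.0005 and 0.000215). Th1 genes rose in 10 of 15 and fell in 1 (11 and 2 adjusted over the list alone, median 1.96, camera adjusted p = 3.27e-06, adjusted p = 0.00991 with an estimated correlation), led by Eomes (4.05 ± 0.47, edgeR adjusted p = 0.000112). Cholesterol synthesis genes rose in 9 of 24 (median 0.95), unfolded protein response genes in 10 of 22 with 1 lower (median 0.63) and p53 targets in 7 of 18 (median 0.69), at camera adjusted p = 4.93e-06, 0.00018 and 0.00498 and adjusted p = 0.406, 0.336 and 0.204 with an estimated correlation. Kit, which fell in wild type, rose in knockout (2.62 ± 0.76, edgeR adjusted p = 0.0316). Tcrg-C1, the most abundant gamma delta T cell marker, rose from 0.247 ± 0.145 to 10.7 ± 7.29 CPM (5.45 ± 1.00, edgeR adjusted p = 0.00222). The highest rises by the rule were Bpifb4 (0 reads at day 7, at least 561-fold), the cadherin gene Cdh1 (ratio 1184, 95% counting interval 212 to 46797), Mcf2l (8.89 ± 0.97), F2rl2 (8.54 ± 1.17), Gzmb, Il24 (7.93 ± 1.54), Pilrb1 (7.90 ± 0.87) and Pigz (7.44 ± 1.03), all at edgeR adjusted p of 0.00514 or less. The lowest were Fcgrt, the neonatal Fc receptor gene (-4.44 ± 0.72), Dapl1, Ms4a4c (-4.26 ± 0.95), Sh3tc1 (-3.80 ± 0.61), Cd9 (-3.78 ± 0.58), Actn1 (-3.74 ± 0.55), Fgfr1 (-3.65 ± 0.56) and the chemokine gene Ccl5 (-3.58 ± 0.79), all at edgeR adjusted p of 0.00712 or less.

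In knockout 1222 genes were higher and 570 lower at day 14 (3143 at an unadjusted p under 0.05; 1067 and 397 by at least 2-fold), while 9 of 31 lists passed camera, 1 with an estimated correlation. All knockout day 7 libraries came from one series of sequencing runs and all knockout day 14 libraries from the other. Day and run are separated only through the wild type, and a run term left 370 genes. With that term 40 of 95 named and called genes kept their calls, among them Il10 (edgeR adjusted p = 0.0367). Calls lost include Il4 (edgeR adjusted p = 0.257), Il5 (0.138), Kit (0.690), Cdh1 (0.104), Plk1 (0.0589), Birc5 (0.0586), Mcm5 (0.0681), Lef1 (0.0502), Tcrg-C1 (0.202), Il24 (0.166), Ms4a4c (0.189) and Ccl5 (0.219). Without knockout day 14 library 2 or 3 the count was 1106 or 1061, and Il4 lost its call without library 3 (edgeR adjusted p = 0.105). Removal of the GC and coding length trend gave 1398 higher and 1947 lower genes, with the median of all genes at -0.15 against 0.02 without it. The time courses of the genotypes shared 836 higher and 366 lower genes, where independent lists would share 161 and 41.8. In opposite directions, 2 genes were higher in wild type and lower in knockout and 3 the other way around. Across genes, which are not independent replicates, the fold changes correlated at a Pearson r of 0.806, and the groups compared share no libraries. Both time courses use the spread estimated jointly over all libraries, so the numbers for independent lists are only a rough guide.

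**Figure D3:**
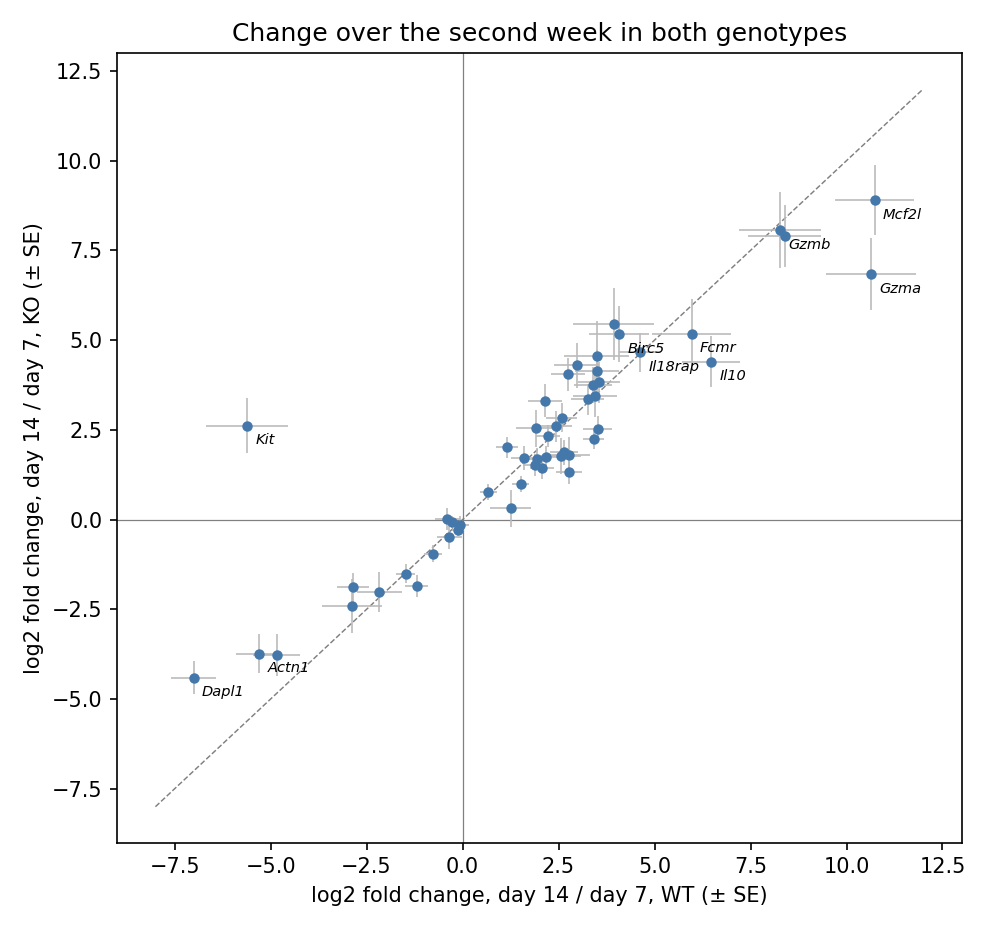
Log2 fold change from day 7 to day 14 in wild type (horizontal, ± SE) and in knockout (vertical, ± SE) for 52 named genes, with a dashed line where both are equal. Kit lies at -5.61 in wild type and 2.62 in knockout, and Dapl1 at -7.00 and -4.40.

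**Figure D4:**
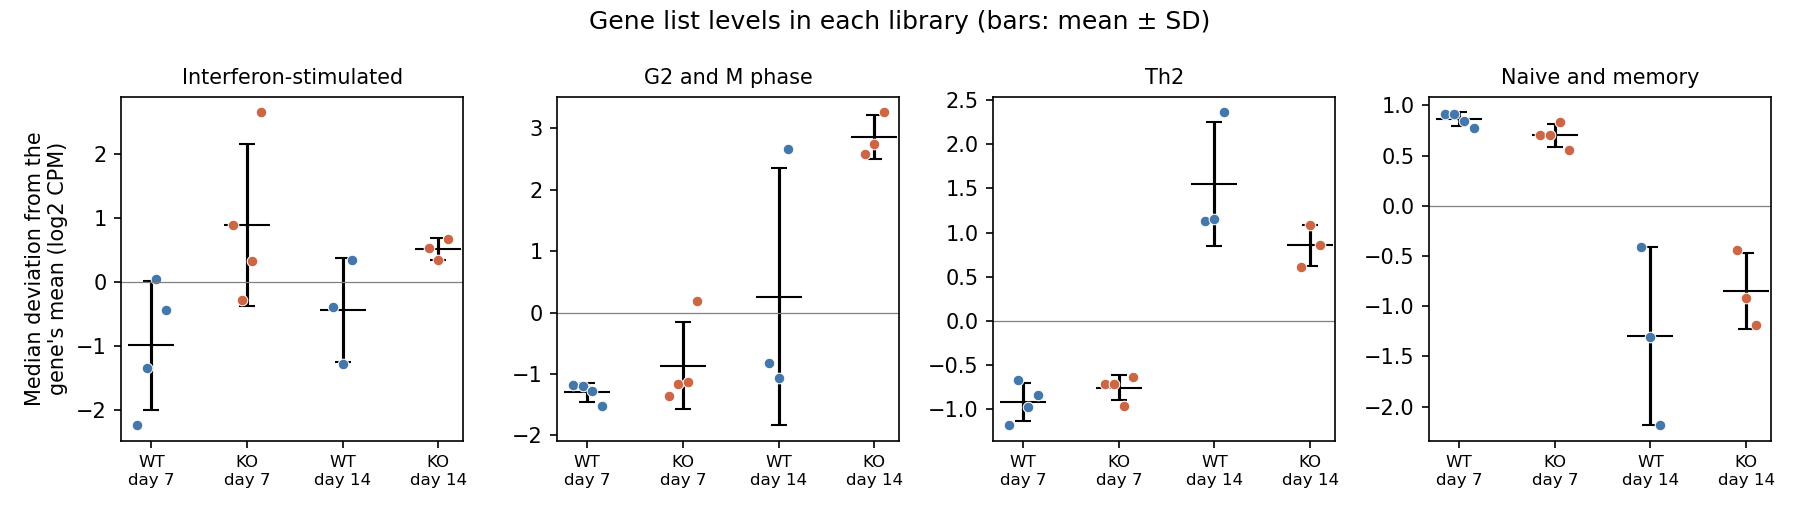
Median deviation of a list's genes from each gene's mean over all libraries (log2 CPM) for 4 lists, with 1 point per library by group (WT wild type, KO knockout) and bars for the mean ± SD. The G2 and M genes run from -1.06 to 2.67 in wild type at day 14 and from 2.59 to 3.26 in knockout at day 14.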

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

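Counts over other splits of the samples, and the trend test on 1 of the day 14 splits, were fixed before their results were seen. All other tests in this part were chosen after the result was seen.

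The genes called near the Argonaute genes at day 7 lay there more often than their number would give (Fisher's exact test, one-sided p = 2.99e-05, 4 of 10 called genes where 0.200 would be expected). Bias from GC content or coding length is argued against, since 4 of the 4 genes keep call and direction with that trend removed. A single deletion from the Argonaute genes to Hdac1 is argued against too, as the 28 genes between had a median log2 fold change of -0.32 with an upper quartile of 0.08. At day 14, 10 of 164 called genes lay in this window (Fisher's exact test, one-sided p = 0.00170). A candidate explanation is sequence of another strain that stayed linked to the engineered locus, and an effect of the missing Argonautes on these genes stays open as well, with neither tested here.

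Interferon-stimulated genes stood higher in knockout at day 7, with wild-type libraries from -2.23 to 0.05 and knockout libraries from -0.28 to 2.65 around each gene's mean (log2). Without knockout library 4 the list's median fell from 2.29 to 1.37, so that library carries part of the difference but not all of it. The GC and coding length trend does not carry it, with a median of 2.13 once it was removed. The ranges of the genotypes overlap, and an exact permutation test on the library values gave a two-sided p = 0.0571 (adjusted p = 0.161). Cells of another type in the knockout cultures may contribute. The summed level of 19 myeloid genes other than Cst3 was 19.5 ± 25.8 CPM in knockout (5.13 to 58.2) and 3.32 ± 1.07 CPM in wild type (2.34 to 4.60). The sums did not overlap between genotypes (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 can give). Their ranges lie close to each other, however, and the knockout mean rests largely on its highest library. The most abundant of the list, Cst3, stood at 280 ± 123 and 129 ± 34.8 CPM, and the cultures were started from sorted naive CD4 T cells per the series text. An effect of genotype on the interferon response stays open.

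The day 14 genotype difference may rest in part on how the libraries of each genotype vary. The real grouping called 165 genes, and 10 splits are too few for a share under 0.05. Of the 10, 2 reached that count: the real grouping itself and the grouping that exchanges wild-type library 3 and knockout library 2. The latter called 2030 genes, which points to a structure of the samples. Exchanged labels are argued against, as wild-type library 3 holds 67 Ago1 reads and knockout library 2 holds 0. The grouping with that exchange sorts the libraries by their slope over GC content. These slopes ran from 0.268 to 0.997 (log2 per 10 percentage points) on 1 side and from -0.460 to -0.00352 on the other. With the GC and coding length trend removed this grouping called 541 genes, the real one 537 and the highest other 571. The outcome written beforehand as evidence against the trend was met by a margin of 4 genes, too small to decide. The fall from 2030 to 541 goes with the trend as a source of this grouping's excess over the real one. What lies behind the GC and coding length trend was not tested. The higher G2 and M genes are not explained by that trend, with a median of 2.06 once it was removed, and in wild-type library 3 they stood at 2.67, inside the range of the knockout libraries (2.59 to 3.26), so that a difference in cell division between cultures, from genotype or from handling, stays open.

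For the counts at day 7 and over time, no other split called as many genes as the real grouping. With 35 splits, 1 of 35 is the smallest share possible. At day 7 the real grouping called 11 genes and the highest of the other 34 splits 0, so that 1 of 35 reached the real count. The 11 include Ago1 and Tyr, each with 0 reads in all day 7 libraries of 1 genotype. Only the real labels separate such genes, so this count says little about the others. In the interaction 1 of 100 splits drawn from 700 reached the real 10, with 9 in the highest other, a margin of only 1 gene. Over time, 1 of 35 splits reached the real count in each genotype, with 2375 against 236 in wild type and 1792 against 735 in knockout. In knockout the sequencing run coincides with day, so the split count there cannot tell day from run.

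Among 227 sets of 4 libraries screened for a single library far from the other 3, 29 had one. The cutoff marks about 1 in 20 for independent, normally distributed values, which would give 11.4. CPM values need not meet these conditions, so 11.4 is only a rough guide. The measure is the gap to the nearest library divided by the whole range. Knockout day 7 library 4 was the distant one in 19. It was higher than the others for Tigit (0.887; 15.8 against 3.61 to 4.99 CPM), Pdcd1 (0.887), Cdc20 (0.873), Ccna2 (0.861), Ecm1 (0.852; 2104 against 354 to 613 CPM), Acat2 (0.885), Cdkn1a (0.908; 140 against 21.8 to 32.7 CPM), Ms4a4c (0.934; 52.6 against 3.28 to 6.52 CPM), Ccl5 (0.878; 68.7 against 7.26 to 14.8 CPM), Gm8797 (0.939), Zbtb8a (0.923), Pilrb1 (0.929) and Acat3 (1), and lower for Gata3 (0.913), Car2 (0.863) and Cxcr3 (0.903). The medians of the Treg (0.960), G2 and M (0.857) and cholesterol synthesis (0.855) lists were higher in it too.

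Other distant libraries at day 7 were knockout library 2 for Mgl2 (0.961), knockout library 1 for Adamtsl4 (0.867) and Sval1 (1), knockout library 3 for Cdh1 (1) and wild-type library 2 for F2rl2 (0.832). Values of 1 came from a single library with reads where the other 3 had 0. In wild type these were nonagouti, Slc30a3, Hba-a1, Mcf2l and Cdh1. In knockout they were Acat3 (1 read, in library 4), Sval1 (3 reads) and Cdh1 (1 read).

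The genotype difference itself differed between days for 10 genes by the interaction term (edgeR quasi-likelihood with Benjamini-Hochberg adjustment): Txk (adjusted p = 0.00169), Gramd3 (0.0152), P2ry1, Kit, Tigit, Bspry, Zbtb8a and Ms4a6b (0.0370 each), Batf3 (0.0372) and Atp1b1 (0.0479). It also differed for 13 lists by camera. More positive at day 14 were G2 and M genes (adjusted p = 3.38e-10, median 1.24), S phase genes (7.29e-10, 0.89), naive and memory genes (4.29e-05, 0.31), mast cell genes (0.0133, 1.21) and other splicing genes (0.0225, 0.28). More negative were myeloid genes (adjusted p = 1.38e-05, median -2.40), inhibitory receptors (1.38e-05, -1.52), interferon-stimulated genes (1.38e-05, -1.26), class II genes (2.36e-05, -1.58), Th2 genes (6.61e-05, -1.36), immediate early genes (0.00128, -0.66), Treg genes (0.0117, -0.01) and cholesterol synthesis genes (0.0430, -0.32). With an estimated correlation 0 of the 13 passed (lowest adjusted p = 0.246 with an estimated correlation). Without wild-type day 14 library 3 the Treg, naive, interferon, cholesterol and mast cell calls ended (camera adjusted p = 0.335, 0.143, 0.167, 0.970 and 0.335). The Treg call also ended without knockout day 14 library 3 (0.0505), the mast cell call without knockout day 14 library 1 (0.0512), the splicing call without any 1 of 4 libraries (0.0706 to 0.169) or with a run term (0.0659) or the GC and coding length offset (0.0627), and the cholesterol call without any 1 of 4 further libraries (0.0763 to 0.493).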

How the results depend on the processing

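The fits with a GC and coding length offset and with limma-voom without sample weights were chosen after seeing the data, and the other alternatives were fixed before the data were examined. Unless said otherwise, the cause of a change was not tested. Counts of called genes are given in the order day 7, day 14, interaction, wild type over time, knockout over time, overlap of the days.

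Counts stayed within 1.5 times under other scaling factors, other count filters and a 2-fold threshold. DESeq2 called 463 genes at day 7, 924 at day 14 and 154 in the interaction, and 62 overlapped between days. It kept 11 of 11, 165 of 165 and 10 of 10 of the genes called by edgeR. limma-voom with sample weights called 5075, 1959, 479, 4609 and 2719 genes, and 856 genes were called in both KO vs WT day 7 and KO vs WT day 14, at weights from 0.148 (wild-type day 14 library 3) to 5.29 (knockout day 7 library 3). Without the weights it called 13, 420, 11, 2440 and 1813 with an overlap of 8, so the weights account for most of the excess. The run term left 79 genes at day 14, 1 in the interaction and 370 in knockout over time, of which 77, 1 and 363 were among the calls without it. Fitting only the compared libraries left 0 genes at day 14, with 1157 at an unadjusted p under 0.05 in edgeR, and an overlap of 0, with fewer libraries behind the estimate of spread. For the interaction these are all libraries, so no separate fit exists. The GC and coding length offset raised day 14 to 537, the interaction to 74, wild type over time to 3822 and knockout over time to 3345, with the common coefficient of variation at 0.263 in place of 0.354.

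Leaving out 1 library gave 8 to 10 genes at day 7, 42 to 2640 at day 14, 1 to 380 in the interaction, 1723 to 3539 in wild type over time, 1061 to 2335 in knockout over time, and an overlap of 6 to 9. The ends of the day 14 range came without knockout library 3 and without wild-type library 3, and without the latter all 165 genes were among the 2640.

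The replicate number as a block gave 15, 236, 7, 2221 and 1607 genes with an overlap of 8. Replicate block terms within each genotype, which cost more degrees of freedom, gave 1129 and 871 over time. Whether the numbers pair the samples is not settled. Correlations of same-numbered libraries ran from -0.456 to 0.417 over 13 pairs, and from -0.116 to 0.417 between the genotypes within a day. Some libraries, but not all, correlated best with their own number. A term for the sex of the mice was not run, since all libraries express Y-linked genes. Their levels were uneven within groups, however. Ddx3y ran from 4.81 to 44.8 CPM in wild type and 5.84 to 22.5 CPM in knockout at day 7. At day 14 it ran from 2.27 to 33.7 and from 3.66 to 18.2 CPM. These levels do not settle whether the sexes were mixed.

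Among list calls 1 reversed, cholesterol synthesis in the interaction with limma-voom and sample weights (adjusted p = 0.938). With an estimated correlation 3 calls held and 56 ended. With voom weights 39 held and 19 ended, with the offset 53 and 6 (among them the microRNA pathway and cytotoxic lists at both days), with the run term 56 and 3, and when leaving out 1 library 467 and 36. Named genes kept their side of the threshold in 1883 leave-one-out tests, lost the call in 293 and gained it in 4. With the run term 203 kept it and 91 lost it, and with the offset 283 kept it, 4 lost it and 5 gained it. Depth limits genes with few reads, such as Il13 and Il5 at day 7.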

Other observations

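The microRNA tests were fixed before their results were seen, and the melanocyte test was chosen after the result was seen.

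Genes of other cell types and tissues were present at differing levels. The list of NK and innate lymphoid cells summed to 5.44 ± 1.00 and 11.9 ± 4.30 CPM at day 7 and to 1466 ± 1807 and 227 ± 196 CPM at day 14, where nearly all of it was Gzma. Myeloid genes, mostly Cst3, summed to 133 ± 35.8 and 299 ± 148 CPM at day 7 and to 377 ± 73.4 and 449 ± 72.1 CPM at day 14. Class II genes, mostly H2-DMa, summed to 88.9 ± 21.4 and 171 ± 98.1 CPM at day 7 and to 117 ± 19.2 and 91.0 ± 29.9 CPM at day 14. Liver genes, added after seeing the data, summed to 35.0 ± 5.56 CPM in wild type and 37.5 ± 4.00 CPM in knockout at day 7, and to 1.06 ± 0.487 and 2.10 ± 1.02 CPM at day 14, with the alcohol dehydrogenase gene Adh1 as the most abundant (15.9 ± 1.56 and 19.5 ± 3.76 CPM at day 7). Mast cell genes summed to 55.2 ± 14.7 and 73.4 ± 14.6 CPM at day 7 and to 6.34 ± 2.09 and 61.6 ± 61.5 CPM at day 14, mostly Cpa3. Gamma delta T cell genes summed to 3.11 ± 1.13 and 4.02 ± 0.476 CPM at day 7 and to 5.56 ± 3.85 and 15.8 ± 8.98 CPM at day 14. B cell genes summed to 1.78 ± 0.640 and 3.11 ± 1.25 CPM at day 7 and to 8.03 ± 5.72 and 8.49 ± 7.23 CPM at day 14, where most of it was Fcmr, which T cells also express. Keratinocyte genes were mostly Krt10, at 3.62 ± 0.822 and 4.28 ± 1.22 CPM at day 7. They summed to 3.62 ± 0.822 and 4.32 ± 1.20 CPM at day 7 and to 1.96 ± 1.00 and 3.73 ± 0.840 CPM at day 14. In each pair the first value is wild type and the second knockout, with n = 4 at day 7 and n = 3 at day 14.

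Single members of the splicing, hypoxia, immediate early and microRNA pathway lists changed over time, while these lists did not pass camera in either time comparison. The splicing factor gene Srsf5 fell by 1.48 ± 0.25 in wild type on the log2 scale and was 2.84-fold lower in knockout (edgeR adjusted p = 0.000890 and 0.00115), while Srsf7 rose in knockout by 2.24 ± 0.49 (0.00649). Jun, an immediate early gene, rose by 2.78 ± 0.33 and 1.32 ± 0.32 (edgeR adjusted p = 6.65e-05 and 0.0124). Pdk1, a hypoxia-responsive kinase gene, fell by 2.25 ± 0.29 in wild type (edgeR adjusted p = 0.000129). Tarbp2, a partner of Dicer, rose by 1.52 ± 0.22 and 0.99 ± 0.22 (edgeR adjusted p = 0.000257 and 0.00604). Other members of these lists went the other way. With the GC and coding length trend removed, 1 microRNA pathway gene rose and 3 fell in wild type. In knockout 1 rose and 4 fell. In the same fit 4 immediate early genes rose and 4 fell in wild type, and 2 rose and 6 fell in knockout. With a run term the knockout calls of Srsf7, Jun and Tarbp2 ended (edgeR adjusted p = 0.209, 0.108 and 0.0810). Il2rb, a chain of the interleukin-2 receptor and a T cell activation gene, rose by 3.26 ± 0.43 and 3.35 ± 0.43 (edgeR adjusted p = 0.000138 and 0.000187).

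If loss of Argonautes relieved microRNA repression, genes with more sites for the 16 abundant T cell microRNA families in their 3' UTRs would stand higher in knockout libraries. The coefficient of log2 CPM per site, over 11378 genes of which 4521 have a site, was lower in knockout instead, by a difference of -0.0183 at day 7 (exact permutation test, two-sided p = 0.114, n = 4 each) and of -0.0272 at day 14 (exact permutation p = 0.1, the smallest that 3 against 3 can give). The tests therefore gave no evidence for general relief of microRNA repression.

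Melanocytes or skin in the knockout cultures could bring Tyr and nonagouti reads. The 8 other melanocyte genes summed to 5.29 ± 0.678 CPM in knockout and 5.18 ± 0.403 CPM in wild type at day 7, and to 4.83 ± 1.11 and 4.65 ± 0.589 CPM at day 14. Most of it was Pmel, and the sums overlap between the genotypes, which argues against melanocytes. Skin was not tested, and keratinocyte genes summed to 3.73 ± 0.840 CPM in knockout and 1.96 ± 1.00 CPM in wild type at day 14, so it stays open. A hypothesis left open is that pigment gene sequences used as visible markers in targeting vectors came along with the engineered chromosome, which the counts cannot test.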
